A study of Homo sapiens with 4 samples.

How the data were processed

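Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in HT1080, a human fibrosarcoma cell line. The labels describe 4 libraries in 4 groups, with 1 library in each group. There were 3 libraries made with an antibody against the transcription factor FOXO3: untreated cells, cells given RSL3, and cells given RSL3 and a second agent abbreviated SRT. The fourth library was titled as RNA polymerase II, in untreated cells. No library of input DNA or of a control antibody is among the 4, so the labels give no measure of background signal. RSL3 is a small molecule that inhibits the lipid peroxidase GPX4 and triggers ferroptosis, an iron-dependent form of cell death. Per the labels' protocols, cells were crosslinked with formaldehyde, chromatin was sheared by sonication, and libraries were made from the eluted DNA by end repair, adaptor ligation and PCR. No molecular identifiers are described.

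The submitters' processing notes name Trim Galore, Bowtie2 2.5.4, SAMtools 1.20, MACS2, bedtools 2.31.1, deepTools 3.5.5 and the build hg38, without a role or an order. How peaks were compared between libraries, how they were assigned to genes, which thresholds applied and how reads mapping to several places were handled are not given in the sources used here. These steps bear directly on a list of pseudogenes, whose sequences resemble those of other genes.

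The values analysed are those of the authors' deposited table for 1 comparison, the untreated FOXO3 library against the FOXO3 library of RSL3 with SRT. The table covers the genes that the authors placed in 1 KEGG pathway map, that for coronavirus disease. Each of its 43 entries gives an Ensembl gene identifier, a direction, the gene's chromosome, start, end and strand, a description and a KEGG orthology number, and 26 entries also give a gene symbol. It holds no peak position, height, fold, p-value or read count, so the depth of each library is unknown here and no error can be attached to any single gene. The direction is the word "Ups", written here as up, in all 43 entries, and the table does not state which of the 2 libraries it refers to. Peak lists and signal tracks were not analysed here. With 1 library per group, no difference between conditions has a replicate check.

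Pseudogenes were recognised from the authors' descriptions, and the parent gene was read from the same description. The parents were checked against the orthology numbers, and no parent had more than 1 number. RefSeq annotation of assembly GRCh38.p14 was used for names, gene types and neighbours. The start of IL12B and both ends of CSF2 were identical in the table and in RefSeq, so both were taken to be on the same coordinates. A listed pseudogene was matched to a RefSeq pseudogene of the same parent by an overlap of at least 1 bp, which succeeded for 39 of 41. In 38 of the 39 both ends lay within 200 bp of each other.

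Before the data were examined, 11 gene lists were fixed: small and large ribosomal subunit, complement, coagulation, renin-angiotensin and entry factors, interferon and antiviral genes, Toll-like receptors and NF-kB, cytokines and chemokines, MAP kinases and AP-1, PI3K with phospholipase C and protein kinase C, and inflammasome and oxidase. The rule for named genes, fixed at the same time, depended on the length of the list and on whether the table gave values per gene. For a list this long without values, it named each gene outside the 2 ribosomal lists. It also named a set number of listed genes from the 2 ribosomal lists, but no such gene was listed. As pseudogenes are in neither list, the rule names all 43 entries. Of these, 2 are counted but not reported by name here. A two-sided Fisher's exact test of large against small subunit genes was also fixed. Planned analyses of fold size, of distance to the transcription start site, and of FOXO motifs had no values or sequence to work on.

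Comparisons added after the list had been seen used as background the 1985 RefSeq pseudogenes named after a gene of the 2 ribosomal lists, of which 39 were listed. It is an approximation, because which pseudogenes the authors' annotation held and gave an orthology number is not given in the sources used here. Rates were compared by two-sided Fisher's exact tests with the conditional odds ratio and its 95% interval. Surroundings were described by the number of protein-coding genes whose body lay within 500 kb of the pseudogene's midpoint, and medians were compared by a two-sided permutation test with 100000 shuffles and a 95% bootstrap interval from 10000 draws. Means were compared with 10000 shuffles. Genes are not replicates, and these tests describe the composition of the list, not the effect of a treatment. P-values were adjusted by the Benjamini-Hochberg method within 4 such comparisons, within 24 chromosomes and within 80 parent genes. Other tests added after the list had been seen were not adjusted. They include those of distance to flanking genes, of correlation and pairs across parent genes, and of shuffles within strata. The permutation and Fisher steps were tested on simulated data, with lists of 39 drawn from the 1985 pseudogenes. Of 100 random lists, the permutation test called 0 and the Fisher test 3. The simulated permutation test compared medians, with fewer shuffles than above and over all pseudogenes. Tests of means and shuffles within strata were not simulated. Of 100 lists weighted to gene-poor places the permutation test called 99, and of 100 lists in which large subunit members were drawn 6 times as readily the Fisher test called 99; smaller weights were not simulated. Alternatives covered the background, the window, the stratification of the shuffles and the chromosomes included. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.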

Results

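FOXO3 occupancy was profiled by ChIP-seq in HT1080 fibrosarcoma cells that were untreated, given RSL3, or given RSL3 with SRT, and RNA polymerase II was profiled in untreated cells, with 1 library in each of the 4 groups. The series concerns a SIRT1 and FOXO3 pathway, fatty acid metabolism and ferroptosis. The gene-level result analysed here is the authors' deposited table of genes marked up between the untreated and the RSL3 with SRT FOXO3 libraries within the KEGG pathway map for coronavirus disease. The library given RSL3 alone and the RNA polymerase II library were not analysed here. Depth is unknown, as the table carries no counts, and it gives a direction for each gene without a size or an error.

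The comparison addresses which genes of this map differed in FOXO3 ChIP signal between untreated cells and cells given RSL3 with SRT. All 43 genes in the authors' deposited table were marked up, which is the only direction that the table covers. Of these, 41 (95.3%) were ribosomal protein pseudogenes, which are copies of ribosomal protein genes that are not annotated as coding for a protein. The other 2 were protein-coding cytokine genes, IL12B and CSF2. No protein-coding ribosomal gene was listed. Annotated ribosomal pseudogenes (1985) far outnumber the protein-coding ribosomal genes (88) and the RefSeq genes of the other fixed lists (130). The share of pseudogenes by itself therefore shows no preference for them.

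IL12B encodes the p40 subunit shared by interleukin-12 and interleukin-23, and CSF2 encodes the growth factor GM-CSF. In the authors' deposited table IL12B (ENSG00000113302) lies on the minus strand of chromosome 5 (hg38) from 159314780 to 159330863. CSF2 (ENSG00000164400) lies on the plus strand of the same chromosome from 132073789 to 132076170. Both belong to the list of 14 cytokines and chemokines fixed before the data were examined, of which the other members, among them TNF, IL6, CXCL8 and CCL2, were not listed. The remaining 8 lists outside the ribosome had no listed gene. These were the lists of complement (23 genes), coagulation (8), renin-angiotensin and entry factors (11), interferon and antiviral genes (27, of which 25 are symbols of protein-coding genes in RefSeq), Toll-like receptors and NF-kB (19), MAP kinases and AP-1 (13), PI3K, phospholipase C and protein kinase C (13), and inflammasome and oxidase (4). Genes absent from a list of genes marked up were either not marked or marked the other way, and the table does not separate these cases. Of the annotated ribosomal pseudogenes, 39 of 1985 were listed. At that rate each of these 8 lists would most likely hold no listed gene, so its absence shows little.

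The pseudogenes came from 29 parent genes, 18 of the large and 11 of the small ribosomal subunit. Large subunit parents accounted for 28 pseudogenes and small subunit parents for 13. RPL21 had the most, with 6 pseudogenes in the authors' deposited table. They were RPL21P110 on chromosome 13 (72703693 to 72704138), RPL21P39 on chromosome 3 (145824257 to 145824739), RPL21P31 on chromosome 2 (175033778 to 175034192), and 3 copies listed by identifier alone. Of the latter, ENSG00000243181 on chromosome 8 overlaps RPL21P80 in RefSeq, ENSG00000237551 on chromosome 7 overlaps RPL21P74, and ENSG00000244662 on chromosome 12 overlaps RPL21P102. RPL23A followed with 3 pseudogenes, RPL23AP22 on chromosome 1 (193756815 to 193757267), RPL23AP44 on chromosome 5 (121575848 to 121576320) and RPL23AP62 on chromosome 11 (112461468 to 112461920). A further 5 parents had 2 pseudogenes each. RPL17 was represented by RPL17P49 and ENSG00000230721, RPL27A by RPL27AP8 and ENSG00000218426, and RPL30 by RPL30P9 and RPL30P13. RPS18 was represented by ENSG00000241204 and ENSG00000213315, and RPS6 by ENSG00000240201 and ENSG00000244669.

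**Figure D1:**
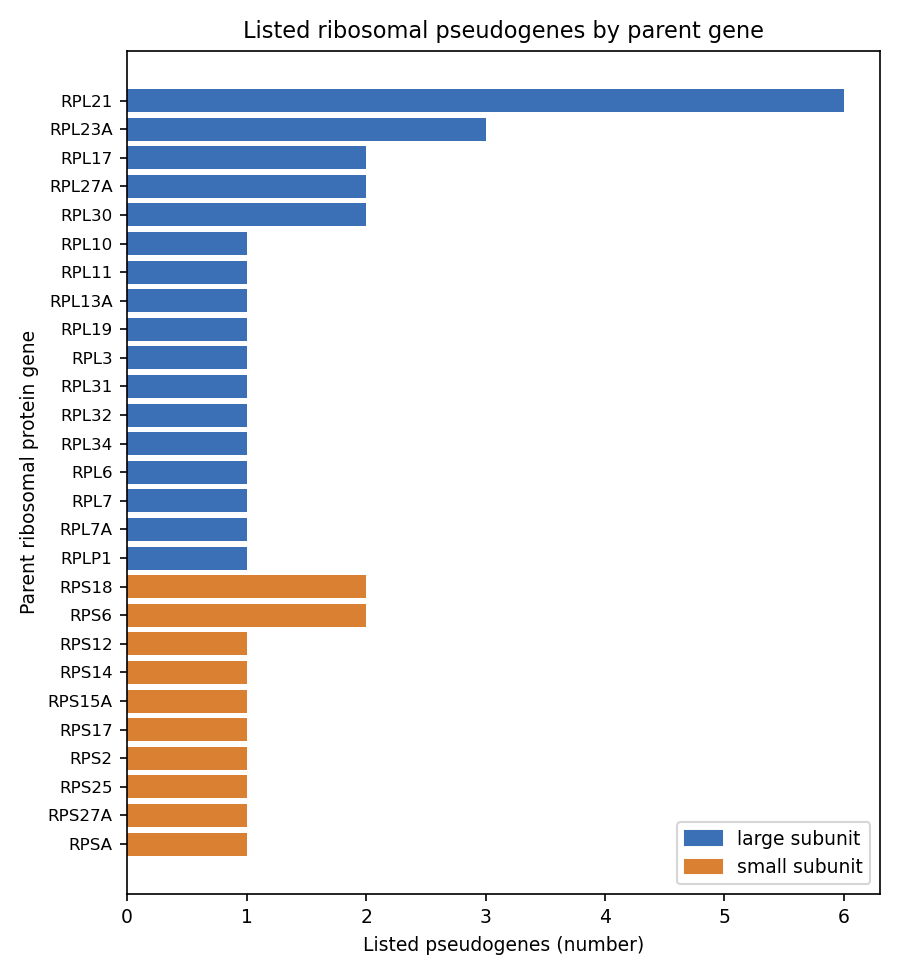
Number of listed pseudogenes (horizontal axis) for 27 of the 29 parent ribosomal protein genes (vertical axis; 2 parents with 1 pseudogene each are not drawn), with large subunit parents in blue and small subunit parents in orange. RPL21 has 6 listed pseudogenes, RPL23A has 3, and 20 of the parents drawn have 1.

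The other 22 parents had 1 pseudogene each. For the large subunit these included RPL3P10, RPL6P15, RPL7P20, RPL7AP66, RPL10P13, RPL13AP7, RPL31P9, RPL32P24, RPL34P26, and copies of RPL11 (ENSG00000244192), RPL19 (ENSG00000241877) and RPLP1 (ENSG00000270830). For the small subunit they included RPS2P6, RPS17P11, RPS27AP16, RPSAP74, and copies of RPS12 (ENSG00000248794), RPS14 (ENSG00000240669), RPS15A (ENSG00000238149) and RPS25 (ENSG00000218472). In all, 17 of the 41 pseudogenes had an identifier and no symbol.

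The planned test of large against small subunit genes found no listed member on either side, 0 of 53 and 0 of 35 protein-coding genes, so no odds ratio could be formed (two-sided Fisher's exact p = 1). Among annotated pseudogenes, a comparison added after the list had been seen, 27 of 1287 large subunit copies (2.10%) and 12 of 698 small subunit copies (1.72%) were listed. The odds ratio was 1.23 with a 95% interval from 0.596 to 2.67 (Fisher's exact p = 0.615, 0.615 after adjustment over 4 comparisons), so no difference between the subunits was detected, and the interval leaves odds ratios up to 2.67 possible. Whether protein-coding ribosomal genes were listed less often than their pseudogenes could not be tested with a list of this length. At the rate of the pseudogenes, 39 of 1985 (1.96%), 1.73 of the 88 protein-coding genes would be listed, and 0, the lowest possible count, gave a Fisher's exact p of 0.409 (adjusted p = 0.546), so no count could have passed as a lower rate.

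RPL21 pseudogenes were listed at 6 of 137 (4.38%) and pseudogenes of all other parents at 33 of 1848 (1.79%), an odds ratio of 2.52 with a 95% interval from 0.847 to 6.23. The unadjusted Fisher's exact p of 0.0478 did not hold after adjustment over 80 parents (0.955). RPL27A, with 2 of only 8 annotated copies listed, had the smallest unadjusted p (0.00978, adjusted 0.782).

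The listed genes lay on 17 chromosomes. Chromosome 5 held 10 of the 43, namely IL12B, CSF2 and 8 pseudogenes, among them RPL6P15, RPL7P20, RPL23AP44, RPS17P11 and the copies of RPL11, RPS12 and RPLP1. Chromosome 8 held 5 pseudogenes: RPL3P10, RPL30P9, RPSAP74 and the copies of RPL21 and RPS18. Among the annotated RefSeq ribosomal pseudogenes, 6 of 114 on chromosome 5 (5.26%) and 33 of 1871 elsewhere (1.76%) were listed, an odds ratio of 3.09 with a 95% interval from 1.04 to 7.69. The Fisher's exact p of 0.0216 did not hold after adjustment over 24 chromosomes (0.275). The copies of RPS12 and RPLP1 on chromosome 5 were the 2 that matched no RefSeq pseudogene and are not in this count. Chromosome 5 did not stand apart. Chromosome 8 (5 of 93, odds ratio 3.10) and chromosome 18 (3 of 37, odds ratio 4.68) had the same adjusted Fisher's exact p of 0.275.

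Of the 41 pseudogenes, 9 lay within a protein-coding gene of RefSeq. The hosts were CKMT2 for the RPS12 copy, NCOA2 and TTC7B for the RPS18 copies, ADAM32 for RPL3P10, ANKRD42 for RPL32P24, SLC25A13 for the RPL21 copy on chromosome 7, FRMPD4 for RPL17P49, SLC2A13 for RPL30P13 and METTL15 for the RPS15A copy. CKMT2 is a mitochondrial creatine kinase, NCOA2 a nuclear receptor coactivator and SLC25A13 a mitochondrial aspartate-glutamate carrier. A further 7 overlapped only a long non-coding RNA gene, among them RPL34P26, which lies at chromosome 13 from 50361410 to 50361763 within DLEU1, and RPL7AP66, which lies within MIR924HG. The remaining 25 overlapped neither. Of the 39 matched pseudogenes, 8 (20.5%, exact Clopper-Pearson 95% interval 9.30 to 36.5%) lay in a protein-coding gene. Of the 1946 other annotated ribosomal pseudogenes, 759 (39.0%, interval 36.8 to 41.2%) did (Fisher's exact p = 0.0196, adjusted over 4 comparisons p = 0.0392). Against only the pseudogenes with a second catalogue name, the call was lost (Fisher's exact p = 0.039, adjusted p = 0.0781).

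Listed pseudogenes also had fewer protein-coding neighbours. A host gene is counted among the neighbours, so this result and that on host genes are not independent. The median number of protein-coding genes within 500 kb was 4 (quartiles 1 and 5.5) for the 39 listed pseudogenes and 8 (quartiles 4 and 13) for the 1946 others, a difference of -4 with a 95% bootstrap interval from -5 to -3. It was larger than chance in a permutation test over pseudogenes (p = 0.00402, adjusted p = 0.0161), and 35 of the 39 listed and 1055 of the 1946 other pseudogenes were at or below the median of all, 8. The gap to flanking genes is the summed distance to the nearest RefSeq gene of any type on each side, not only protein-coding ones. A pseudogene overlapped by another gene of any type counts as having no gap. When labels were shuffled only among pseudogenes of a like gap to their flanking genes, the difference in medians did not pass the permutation test (p = 0.326). The means over all listed and all other pseudogenes were 3.97 and 10.2 genes, a difference of -6.21. It passed the same shuffles (permutation p = 0.004), which by themselves gave a difference of -2.93 on average. IL12B and CSF2 had 4 and 13 protein-coding genes within 500 kb, each counting itself.

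**Figure D2:**
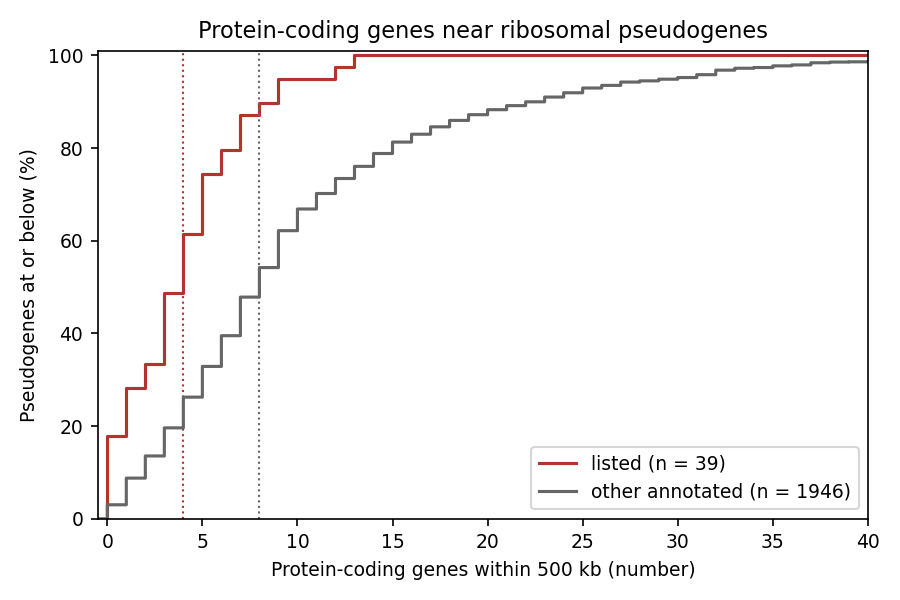
Cumulative share of pseudogenes (vertical axis, percent) with at most a given number of protein-coding genes within 500 kb (horizontal axis), for 39 listed (red) and 1946 other annotated ribosomal pseudogenes (grey), with dotted lines at the medians of 4 and 8. The horizontal axis stops before the highest value of the other pseudogenes, 61, while the highest listed value is 13.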

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

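All alternatives in this paragraph except distinct gene symbols, ribosomal paralogs and the planned smaller gene background were chosen after seeing the data. The list held 43 genes with 31 distinct orthology numbers, but 26 distinct symbols, as 17 genes had none, and 2 genes when restricted to protein-coding ones. The planned subunit test (Fisher's exact test) gave p = 1 with and without the paralogs and on the planned smaller background, with no listed gene in any version, and therefore says nothing about stability. The difference in median protein-coding neighbours lay between -6 and -2 under the 5 alternatives that changed the window, the background, the chromosomes or the positions (permutation p from 0.00304 to 0.00887), and was -8 when genes of every type were counted (permutation p = 0.00189). The other 2 alternatives changed only how labels were shuffled, which leaves the difference as it was: within parent genes the permutation test passed (p = 0.0041), and within 5 strata of the gap to flanking genes it did not (permutation p = 0.326), as shuffled labels there gave a difference in medians of -2.59 on average against the observed -4. The difference in means in the same strata, -6.21 against -2.93 in shuffled labels, passed (permutation p = 0.004), so the call depends on the statistic. A background restricted to 1812 pseudogenes with a second catalogue name left the subunit comparison without a call and ended that of host genes (Fisher's exact p = 0.039, adjusted p = 0.0781, odds ratio 0.443 with a 95% interval from 0.173 to 1.00 against 0.404 before); the odds ratio moved little and the interval came to include no difference. RPL21 and chromosome 5 stayed under an unadjusted 0.05 (Fisher's exact p = 0.0372 and 0.0175). They are the parent and the chromosome with the most listed members, and neither passed adjustment on the full background (adjusted Fisher's exact p = 0.955 and 0.275). The repeat on much the same pseudogenes is therefore no separate support. The planned stricter threshold, the mean value per gene, other distances to the start site and other motif forms were not run, as the table has no values or peak positions and no genome sequence was used here. No paired analysis was possible because each group has 1 library. The depth of the libraries is unknown, so what it limits cannot be stated.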

Other observations

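The tests of position and of parent genes below were chosen after the list was seen, with what each would show written before its result, except the comparison within strata of the gap, which was added later. The listed pseudogenes were short, with a median annotated length of 453 bp and 40 of 41 under 1200 bp. The exception was RPL13AP7, annotated over 19936 bp in the authors' deposited table. No gene of the interferon, complement or Toll-like receptor lists stands beside them, and without the pseudogenes the list for this pathway map would hold IL12B and CSF2 alone.

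The first pattern is that the listed ribosomal pseudogenes, such as RPL21P110, RPS27AP16 and RPL31P9, sit where fewer protein-coding genes are annotated (medians 4 against 8 genes, permutation p = 0.00402); this test defines the pattern and is no separate evidence against a draw regardless of position. A candidate explanation is that peaks were assigned to the nearest annotated gene, so that an isolated pseudogene collects peaks from a wide stretch of DNA: the summed gaps to the flanking genes averaged 122 kb for listed and 41.2 kb for other pseudogenes, a ratio of 2.95 (95% bootstrap interval 1.86 to 4.18), and the difference of 80.3 kb exceeded the 29.0 kb that labels shuffled within 5 strata of gene density gave on average (permutation p = 0.0053). A pseudogene overlapped by another gene entered with a gap of 0 kb, so the means and their ratio mix gap length with the share overlapped. The medians were 71.1 and 0 kb, and 16 of the 39 listed pseudogenes (41.0%, against 50.8% of others) overlapped another gene, so isolation does not describe those 16. In the opposite direction, within strata of the gap the difference in median protein-coding neighbours did not pass a permutation test (p = 0.326) but that in means did (permutation p = 0.004), so the gap may account for part of the pattern and is not shown to account for all of it. How the authors assigned peaks is not given in the sources used here, and the selection of pseudogenes by their annotation, or a real difference in FOXO3 occupancy of gene-poor DNA between the untreated and the RSL3 with SRT cells, stays open and untested without peak positions.

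The second pattern is the spread over parent genes. Parents with more annotated pseudogenes had more listed members (Spearman rho = 0.337 across 80 parents, 95% bootstrap interval 0.132 to 0.526, permutation p = 0.0029). A draw in proportion to copy number would also give a positive correlation. The rho under such a draw was not computed, so whether the list departs from it was not tested. If reads shared between near-identical copies brought members in together, listed pairs from one parent might exceed chance. There were 23 such pairs, against a mean of 17.1 and a range from 9 to 27 (5th to 95th percentile) in 10000 random draws of 39, so shared reads and independent listing cannot be told apart in a list of this size. How multiply mapping reads were treated, and whether FOXO3 binding at any one copy changed, cannot be read from this table.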
